A study of Homo sapiens with 3 samples.

How the data were processed

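RNA from the human glioma cell line T98G was measured on 3 Agilent 2-colour whole-genome expression arrays. Each array held 1 replicate of cells with BAP-tagged PCBP2 (BAP-PCBP2), labelled with Cy3, and 1 replicate of control cells with BAP-tagged GFP (BAP-GFP), labelled with Cy5, per the labels. The series title describes the material as RNA immunoprecipitates (RIP), in which RNA bound to a tagged protein is recovered, while the extraction protocol in the labels describes total RNA taken with Trizol. The series design gives 3 biological replicates of each condition. All 3 arrays had the same dye orientation in the channel labels, although the description speaks of replicates for each dye orientation. The channel labels were followed, and the ratios of the 3 arrays correlated positively. PCBP2 itself was higher in the channel labelled BAP-PCBP2 on all 3 arrays (5.06, 5.14 and 6.05), which exchanged labels would turn into a fall of the tagged gene. With 1 orientation, a dye effect particular to a probe could not be separated from the difference between the conditions. Replicates 2 and 3 shared a slide and a scan day, and replicate 1 was on another slide and another day.

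The deposited scanner files hold spot intensity, as mean signals and median local background in each channel, and were written by Agilent Feature Extraction 10.5.1.1 per the file headers, although the submitters' processing notes name version 7.0. They also hold processed intensity values, background-subtracted, spatially detrended and dye-normalised per the file headers, and a deposited log10 ratio of Cy5 over Cy3. The series matrix holds a deposited log2 ratio whose direction and scale were not stated. Set against the scanner files, 99.978%, 99.9366% and 99.978% of its values on arrays 1, 2 and 3 matched log2 of Cy3 over Cy5 within 0.01. A match was to the ratio of processed signals or to the deposited log10 ratio turned to that direction and scale. Column medians were −0.15, −0.24 and −0.06, so scale, centring and direction were settled. Probe coordinates are those of hg18/NCBI36 per the file headers.

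Each array had 45015 spots, of which 43376 were not controls, and 41000 probes. Of these probes, 25398 were named by their accession, 2510 by symbol and 789 by an older symbol in the RefSeq gene table for GRCh38.p14, from which only names were taken. The other 12303 kept the name in the files. Median intensity in the PCBP2 channel was 114, 112 and 85.8 on arrays 1 to 3, and in the GFP channel 90.3, 90.4 and 144. The share of spots well above background was 75.9%, 68.9% and 60.6% in the PCBP2 channel and 69.2%, 53.2% and 66.1% in the GFP channel. No spot was saturated, and 102, 130 and 132 spots were marked as outliers by the scanner software and left out. The number of arrays, 3, limits the precision of every value.

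Background was corrected by normexp with an offset of 50 and ratios were normalised within each array by loess, with control and outlier spots at weight 0. All ratios were turned to log2 of BAP-PCBP2 over BAP-GFP. Spots of a probe were averaged. A probe was kept if it was well above background in at least 1 channel, the same on all 3 arrays, and the brightest probe stood for a gene. This left 18226 genes, 13028 of them with a gene symbol and the rest with a clone, transcript cluster or probe name. Among 4691 genes with several kept probes, 1186 were called, and the probes of 157 of these differed in sign. A gene not above background in 1 condition on any array has only a bound. It was given as at least N-fold, from the normalised mean of the bright channel against the higher, per array, of the dim probe's own signal and the lowest signal well above background, after loess and between-array scaling of average intensity. This bound is open to dye bias.

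The ratio against 0 was tested with limma (lmFit with an intercept and eBayes) and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05 on the adjusted p. Because each array pairs 1 replicate of each condition, this fit carries the replicate as a block. Errors are SDs over the 3 arrays. Genes at least 2-fold apart on every array were also counted, beside the count after shuffling each array over genes. Gene lists were tested with camera at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry, each adjusted over the 26 lists. The lists were the PCBP family with HNRNPK, mRNAs reported as PCBP targets, LIM proteins, ribosomal proteins, translation factors, nuclear-encoded respiratory chain, proteasome, replication-dependent histones, spliceosome and hnRNP proteins, ZNF zinc fingers, interferon-stimulated genes, unfolded protein response, heat shock, immediate early genes, cell cycle, apoptosis and related genes, iron handling, extracellular matrix, glioma signalling, cytoskeleton and adhesion, and markers of neurons, oligodendrocytes, microglia and macrophages, astrocytes, endothelium and erythroid cells.

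The grouping, tests, lists and the rule for named genes were set before the data were examined. The rule names PCBP1 to PCBP4, HNRNPK and FHL1 to FHL3. It adds the 12 highest and 12 lowest genes past the threshold with the same sign on all arrays, leaving out probes without a gene symbol. In each list it takes up to 4 called members with the largest ratios, or 2 members where none was called. Other genes named were chosen after their values were seen, and this is said where they appear. Some genes that the rule names are not reported here. Alternatives covered the normalisation, background correction, filter on dim probes, choice of probe, left-out replicates, slide, variance model, array weights, channel pairing, series matrix values and list tests. A planned test of C-rich runs in whole mRNAs and 3′ UTRs was not run, since no transcript sequences were used here. Probe sequences were examined in its place, which was decided after seeing the data; within this, the tests of runs of C and of a dye effect alike for all genes were set before their own results were seen.

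The fit was tested on simulated ratios for the 18226 genes of the BAP-PCBP2 over BAP-GFP comparison, with 50 genes changed at each size. Of genes with a true log2 ratio of 2 or −2, 100% were called, with median estimates of 1.60 and −1.49. At 1 and −1, 96% were called in each direction, with medians of 0.76 and −0.79, so the offset pulls ratios towards 0. Of 197 calls, 1 was an unchanged gene (0.508%). The simulation gave every gene the same independent spread (SD 0.243), changed few genes, as many up as down, and held no dye effect. These rates therefore do not carry over to the arrays themselves, where most calls were higher and spreads differed between genes. R 4.3.3, limma 3.58.1, the data.table package 1.17.8, Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6 were used.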

Results

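The arrays compared RNA of T98G, a human glioma line, with BAP-PCBP2 against RNA with BAP-GFP as the control. The series title describes it as RIP and the extraction protocol as total RNA, so a higher ratio may mean more recovery with the protein or more RNA in the cells. PCBP2 is a KH-domain protein that binds runs of C in RNA. The question of the comparison is which transcripts were higher with BAP-PCBP2. There were 3 replicates of each condition, paired on 3 arrays of 41000 probes, and 18226 genes were measured well enough to test. Ratios are log2 of BAP-PCBP2 over BAP-GFP, so positive values are higher with PCBP2, and errors are SDs with n = 3 arrays. Adjusted p-values are limma's.

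The mRNA of PCBP2 itself was among the most raised transcripts, 42.8-fold higher with BAP-PCBP2 (log2 5.42 ± 0.55, SD, n = 3, adjusted p = 0.000179). Its 3 probes, all on chromosome 12, gave 5.42 (52135539 to 52135989), 5.44 (52136028 to 52139357) and 4.38 ± 0.20 (52160485 to 52160544). The labels do not say which part of the PCBP2 transcript the tagged construct carried. The related poly(C)-binding genes PCBP1 and PCBP4 rose 20.6-fold (4.37 ± 0.46, adjusted p = 0.000188) and 10.0-fold (3.33 ± 0.23, adjusted p = 0.000182). A second PCBP1 probe gave 3.69. PCBP3 was at 0.10 ± 0.15 (adjusted p = 0.630), with its GFP channel above background on 1 array, and HNRNPK, another KH-domain protein, was at −0.39 ± 0.50 (adjusted p = 0.249), with −0.68 from its other probe. Of the 5 measured genes of this list 3 rose (3 adjusted over the list alone), and the list as a whole was higher (median 3.33, camera adjusted p = 0.0267), but not with an estimated correlation (adjusted p = 0.549 with an estimated correlation). PCBP2 is the tagged gene, so its own rise could come from the construct and is not independent evidence for this list. Whether probes of the related genes also take up PCBP2 RNA was not tested.

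FHL3, a LIM-domain protein, rose 9.72-fold with little spread between arrays, from 3.24 to 3.33 (mean 3.28 ± 0.05, adjusted p = 0.000179, chromosome 1, 38235984 to 38236043). Its relatives FHL1 (0.27 ± 0.24, adjusted p = 0.249) and FHL2 (−0.33 ± 0.83, adjusted p = 0.504) did not pass. With 1 array left out, FHL1 lay between 0.14 and 0.36 and FHL2 between −0.60 and 0.15. FHL3 was named before the data were examined as an mRNA reported to be a PCBP2 target. It may have been picked from these arrays, so its rise is not independent evidence for either list that holds it. Of 15 LIM proteins 8 rose and none fell (9 higher and 1 lower adjusted over the list alone), among them zyxin (ZYX, 3.63 ± 0.52, 12.4-fold), TGFB1I1 (2.12 ± 0.20) and paxillin (PXN, 2.00 ± 0.72), which sit at focal adhesions. The other probes of PXN were at 0.49 and 0.64, and the mean of its probes at 1.04. The LIM list was higher as a whole (median 0.95, camera adjusted p = 0.0153), with adjusted p = 0.549 with an estimated correlation. Relative to all genes its median was 0.93, and 0.45 to 1.66 over the alternatives. Of 22 measured mRNAs reported as PCBP targets 8 rose and 1 fell (8 and 2 adjusted over the list alone). Among them the cell cycle inhibitor CDKN1A rose by 1.79 ± 0.51 and the collagen-modifying enzyme PLOD3 by 1.79 ± 0.86, while P4HA1, a prolyl hydroxylase chosen after its value was seen, fell (−0.63 ± 0.23). The list did not pass (median 0.32, camera adjusted p = 0.0954), but did without the filter on dim probes (adjusted p = 0.0241, 0.103 from the median of all genes against 0.297) and without replicate 1 (adjusted p = 0.0454). The call of P4HA1 was lost without replicate 1 (adjusted p = 0.177). The calls of PLOD3 and P4HA1 were lost without replicate 2 (adjusted p from 0.0643 to 0.0947). The call of P4HA1 was lost without replicate 3 (adjusted p = 0.066).

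**Figure D1:**
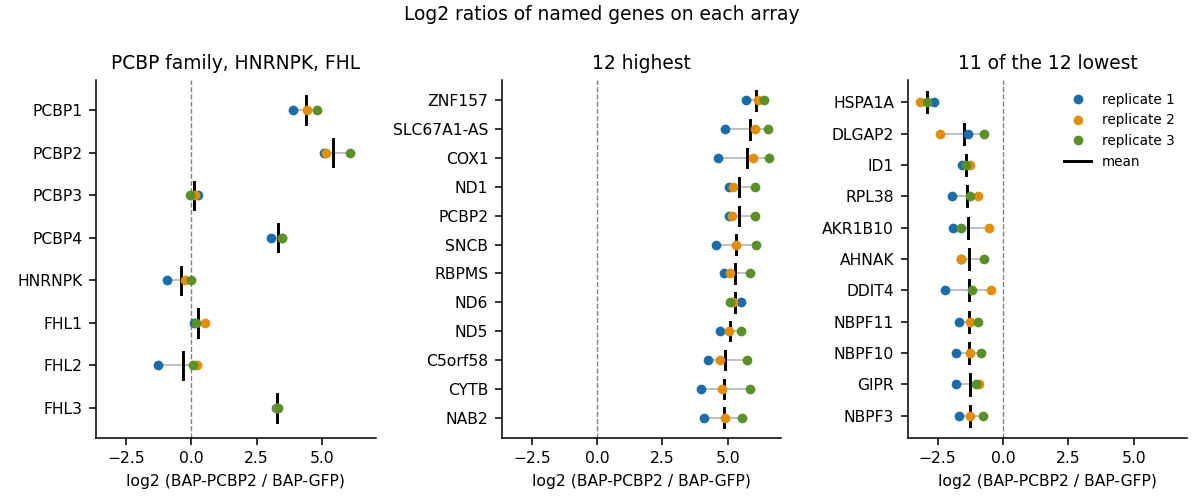
Log2 ratio of BAP-PCBP2 over BAP-GFP (x axis) for the PCBP family, HNRNPK and FHL genes and for the 12 highest and 11 of the 12 lowest genes, with a point per replicate, a grey line over their range and a black bar at the mean. PCBP2 lies near 5.42, the points of FHL3 nearly coincide at 3.28, and HSPA1A lies at −2.90.

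Most called transcripts were higher with PCBP2. Of the 18226 genes, 3594 rose (19.7%) and 522 fell (2.86%), so 87.3% of calls were higher. Loess sets the bulk of ratios on each array near 0 (medians 0.03, 0.05 and 0.11), so rose and fell are relative to that centre. A shift shared by most transcripts would not be seen, and a gene that fell may only have been less raised than most. Among genes with a symbol, 2606 rose and 249 fell. The median log2 ratio was 1.22 among genes that rose and −0.66 among those that fell, and 233 genes rose at least 8-fold. At an unadjusted p under 0.05, 4758 were higher and 1627 lower. On every array, 1561 genes were at least 2-fold higher and 5 at least 2-fold lower, against 38.7 and 0.02 after shuffling. Shuffling breaks all agreement between arrays, so the excess shows only that the arrays agreed. With 1 dye orientation, a dye effect particular to a probe would also repeat on every array. The 5 lower were HSPA1A, ID1, ADAMTS7 (−1.22 ± 0.23), and 2 probes without a gene symbol. ADAMTS7, a secreted metalloprotease chosen after its value was seen, had another probe at 1.91, and the mean of its probes was 0.35. Among 90 of the genes that rose, the GFP channel was not well above background on any array, so their fitted ratios are uncertain and only a bound could be set on each fold.

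The split between higher and lower depended on the scaling. It was 99.8% higher with median centring, which called 1273 genes higher and 2 lower, 72.4% with the scanner's processed signals and 72.7% with the series matrix values, where the median of all genes moved to −0.17 from 0.02. With a variance trend over intensity and robust estimation, 4309 genes rose and 560 fell. Without replicate 2, 2018 genes rose and 90 fell, and without replicate 1, 73 fell. Ratios correlated across genes at r = 0.859 between replicates 1 and 2, 0.791 between 1 and 3 and 0.775 between 2 and 3, which shared a slide (Spearman 0.714, 0.673 and 0.509); genes are not independent replicates.

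**Figure D2:**
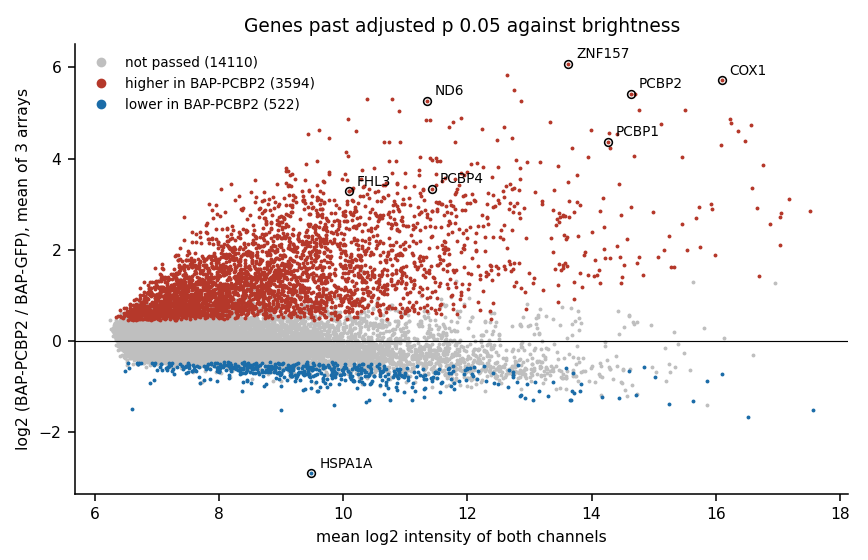
Mean log2 ratio of BAP-PCBP2 over BAP-GFP (y axis) against mean log2 intensity (x axis) for the 18226 genes, with genes past the adjusted threshold coloured by direction. The 3594 higher genes reach 6.07 and the 522 lower genes reach −2.90.

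The highest transcript was ZNF157, a zinc finger protein, at 67.0-fold (6.07 ± 0.36). It was followed by the antisense transcript SLC67A1-AS (5.83 ± 0.84, 56.8-fold, named SLC22A18AS in the files). Mitochondrially encoded transcripts of the respiratory chain filled 5 of the 12 places, with COX1 at 5.71 ± 0.99 (52.5-fold), ND1 at 5.42 ± 0.54, ND6 at 5.26 ± 0.23, ND5 at 5.07 ± 0.40 and CYTB at 4.86 ± 0.95. The COX1 probe is placed at a nuclear copy of the sequence on chromosome 1 (557430 to 557489), and such copies cannot be told from the mitochondrial transcript by this probe. The synaptic protein gene SNCB rose by 5.32 ± 0.77, the RNA-binding protein gene RBPMS by 5.26 ± 0.54, and C5orf58, named LOC133874 in the files, by 4.88 ± 0.76. NAB2, a corepressor of EGR transcription factors, was at 4.84 ± 0.72 from its brightest probe and at 0.29 from the other.

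The lowest transcript was HSPA1A, an inducible Hsp70 chaperone, which fell by 2.90 ± 0.26 on the log2 scale (adjusted p = 0.000222). HSPA1A has a near-identical copy, HSPA1B, which its probe may not tell apart. ID1, an inhibitor of helix-loop-helix transcription factors, fell by 1.41 ± 0.17, the ribosomal protein gene RPL38 by 1.38 ± 0.52, the aldo-keto reductase gene AKR1B10 by 1.35 ± 0.72 and the stress-induced gene DDIT4 by 1.29 ± 0.89. DLGAP2, named C8orf68 in the files, was not well above background with PCBP2 on any array and was at least 2.30-fold lower (adjusted p = 0.0206). NBPF11 (−1.29 ± 0.36), NBPF10 (−1.29 ± 0.49) and NBPF3 (−1.24 ± 0.47) belong to a repeated gene family and are uncertain, since their probes may share targets. Their other probes were nearer to 0, at −0.63 for NBPF11, −0.80 for NBPF10 and −0.55, −0.52 and −0.22 for NBPF3. AHNAK (−1.30 ± 0.51), a large scaffold protein, had 5 probes from −1.30 to 0.30, and the receptor gene GIPR (−1.24 ± 0.49) had another probe at 0.46 and no call for the mean of its probes (−0.39, adjusted p = 0.111). All of the genes named here kept their call with a variance trend and robust estimation, and all but HSPA1A and AHNAK lost it with median centring. The calls of AKR1B10 and DDIT4 were lost without replicate 1 (adjusted p from 0.0544 to 0.0797, DDIT4 −0.82). The calls of DLGAP2, NBPF10, NBPF3 and AHNAK were lost without replicate 2 (adjusted p from 0.0619 to 0.0743). The call of DDIT4 was lost without replicate 3 (adjusted p = 0.0636).

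With its preset correlation, camera placed ribosomal protein and replication-dependent histone transcripts lower as groups, but not with an estimated correlation, and fry called neither (adjusted p = 0.342 and 0.258). Of 87 ribosomal protein genes 8 fell and none rose (2 lower adjusted over the list alone), with RPL38, RPS14 (−1.14 ± 0.36), RPS27 (−0.94 ± 0.55) and RPS3 (−0.91 ± 0.46) the lowest. The list's median was −0.63 (camera adjusted p = 6.4e-14, and adjusted p = 0.549 with an estimated correlation), with medians of −1.37, −0.12 and −0.39 on replicates 1 to 3. The 4 probes of RPS14 ranged from −1.23 to 0.34. Of 61 histone genes 9 fell and 1 rose (38 and 1 adjusted over the list alone), including H3C7 (−1.06 ± 0.66), H3C10 (−1.04 ± 0.40), H2AC7 (−0.89 ± 0.61) and H3C11 (−0.88 ± 0.30), while H2BC12, chosen after its value was seen, was at 0.57 ± 0.24. The other probes of H3C7 were at 0.11 and −0.14, and the mean of its probes was not called (−0.36, adjusted p = 0.0918). The histone median was −0.73 (camera adjusted p = 4.26e-14, and adjusted p = 0.549 with an estimated correlation), with −1.48, −0.44 and −0.41 on the replicates. Histone genes are near-identical copies of one another, so single members are uncertain. Both lists kept their direction and call under every scaling tried, although with median centring none of the members named here kept its call. Without replicate 1, their medians lay −0.33 and −0.44 from that of all genes, against −0.65 and −0.75 with it. The calls of RPS27, RPS3, H3C7, H2AC7, H3C11 and H2BC12 were lost without replicate 1 (adjusted p from 0.0648 to 0.253, H3C7 −0.69 and H2AC7 −0.54). The calls of RPS27, RPS3, H3C7, H3C10, H2AC7, H3C11 and H2BC12 were lost without replicate 2 (adjusted p from 0.055 to 0.126). The call of H2BC12 was lost without replicate 3 (adjusted p = 0.0689).

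The chaperone and proteasome lists were also placed lower by camera at its preset correlation only, with members moving both ways. Of 17 heat shock genes 6 fell and 2 rose (10 and 2 adjusted over the list alone). HSPA1A and HSP90AB1 (−1.03 ± 0.26) fell, while the small heat shock protein gene HSPB1 (1.85 ± 0.40) and the co-chaperone gene BAG3 (1.82 ± 0.31) rose. The median was −0.57 (camera adjusted p = 0.000269), with adjusted p = 0.549 with an estimated correlation. Of 37 proteasome genes 3 fell and 2 rose (2 and 2 adjusted over the list alone), with PSMA7 at −0.82 ± 0.42, PSMB3 at −0.75 ± 0.18, PSMD13, chosen after its value was seen, at −0.61 ± 0.27, and the regulatory subunit PSMD11 at 2.74 ± 0.25. PSMD5 was at 1.29 ± 0.24 from its brightest probe and −0.06 from the other. The proteasome median was −0.36 (camera adjusted p = 0.000269), or −0.38 from that of all genes against −0.25 without replicate 1, with adjusted p = 0.549 with an estimated correlation. The calls of PSMA7, PSMB3 and PSMD13 were lost without replicate 1 (adjusted p from 0.0865 to 0.219). The calls of HSP90AB1, PSMA7, PSMB3 and PSMD13 were lost without replicate 2 (adjusted p from 0.0569 to 0.147). The call of PSMD13 was lost without replicate 3 (adjusted p = 0.0774).

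Genes of translation, respiration, splicing and the cell cycle had medians below 0 although several members rose. Camera sets a list against the other genes, and the mean log2 ratio of all genes was 0.24, beside a median of 0.02. The means of the translation, respiratory and cell cycle lists were −0.04, −0.07 and −0.03. A list that camera placed lower was therefore lower relative to the other genes, which need not be a fall. Of 34 translation factors 6 rose and 4 fell (6 and 6 adjusted over the list alone). The poly(A)-binding protein gene PABPC1 (2.33 ± 1.00), EIF1 (2.29 ± 0.74), EIF4G2 (2.01 ± 1.06) and EIF5A (1.85 ± 0.24) rose, and EEF1A1 (−1.10 ± 0.71), EEF2 (−0.90 ± 0.61), EIF3B (−0.64 ± 0.33) and EIF3K (−0.63 ± 0.29), chosen after their values were seen, fell. The list's median was −0.33 (camera adjusted p = 0.010), with adjusted p = 0.549 with an estimated correlation. Of 87 nuclear-encoded respiratory chain genes 5 rose and 2 fell (4 and 0 adjusted over the list alone), with ATP5MC2 at 1.60 ± 0.29, NDUFA7 at 1.27 ± 0.35, NDUFS7 at 0.79 ± 0.19 and DMAC2, an assembly factor listed through its older name, at 0.76 ± 0.02. Chosen after their values were seen, NDUFA3 (0.52 ± 0.17) was the other that rose and SDHA (−0.58 ± 0.02) and ATP5MC3 (−0.59 ± 0.29) fell. The median was −0.16 (camera adjusted p = 0.00986), with adjusted p = 0.686 with an estimated correlation. Relative to all genes it was −0.18, with −0.09 and no call without replicate 1 (adjusted p = 0.174) and −0.31 without replicate 2. The translation list lost its call without replicate 3 (adjusted p = 0.0549). The calls of EEF1A1, EEF2, EIF3B, EIF3K, DMAC2, NDUFA3, SDHA and ATP5MC3 were lost without replicate 1 (adjusted p from 0.0533 to 0.267, EEF2 −0.55). The calls of EIF4G2, EEF2, EIF3B, EIF3K, NDUFS7, DMAC2, NDUFA3, SDHA and ATP5MC3 were lost without replicate 2 (adjusted p from 0.0601 to 0.157). The call of EEF1A1 was lost without replicate 3 (adjusted p = 0.0803).

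Of 74 spliceosome and hnRNP genes 11 rose and 1 fell (10 and 0 adjusted over the list alone). SF3B4, a subunit of the U2 particle, rose 20.6-fold (4.37 ± 0.70), followed by SNRPA (2.84 ± 0.35), CLASRP (2.65 ± 0.72) and HNRNPUL1 (2.53 ± 0.36), and HNRNPR, chosen after its value was seen, fell (−0.49 ± 0.11). CLASRP had 2 other probes at 0.11 and 0.09 and was below 0 with the processed signals. The list's median was −0.18 and its mean 0.13, against a mean of 0.24 for all genes. Camera placed it lower than the other genes (adjusted p = 0.0377), with adjusted p = 0.549 with an estimated correlation. Of 47 cell cycle genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), with the phosphatase gene CDC25B at 3.10 ± 0.34, the transcription factor gene FOXM1 at 2.73 ± 0.83, TK1 at 1.02 ± 0.14 and HMGB2 at −0.93 ± 0.26. PLK1 (0.91 ± 0.30), CDT1 (0.85 ± 0.18), CENPF (−0.82 ± 0.35) and TOP2A (−0.65 ± 0.15), chosen after their values were seen, were the other called members. The median was −0.18 (camera adjusted p = 0.00986), with adjusted p = 0.549 with an estimated correlation. Median centring and the smaller normexp offset each ended the calls of the translation, respiratory and spliceosome lists. The spliceosome list was not called without replicate 1 (adjusted p = 0.169, −0.128 relative to all genes against −0.197), without replicate 3 (adjusted p = 0.066) or with a variance trend (adjusted p = 0.0584). Without replicate 1 the cell cycle median went from −0.20 to −0.14 relative to all genes. The calls of HNRNPR, PLK1, CENPF and TOP2A were lost without replicate 1 (adjusted p from 0.056 to 0.146). The calls of HNRNPR, PLK1 and TOP2A were lost without replicate 2 (adjusted p from 0.0653 to 0.175). The call of HNRNPR was lost without replicate 3 (adjusted p = 0.0844).

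Several immediate early and cytoskeleton and adhesion genes rose, where 19.7% of all genes did. Camera called neither list, while fry called the immediate early list higher (adjusted p = 0.0274). Of 28 immediate early genes 8 rose and 1 fell (9 and 1 adjusted over the list alone). The AP-1 subunit gene FOSL1 rose 18.9-fold (4.24 ± 0.52), ZFP36, which promotes mRNA decay, 8.40-fold (3.07 ± 0.14), EGR1 by 3.06 ± 0.77 and BTG2 by 2.34 ± 0.60, and JUN, chosen after its value was seen, fell (−0.93 ± 0.08; list median 0.14, camera adjusted p = 0.155). Of 38 cytoskeleton and adhesion genes 11 rose and 2 fell (17 and 2 adjusted over the list alone). The actin regulators PFN1 (2.77 ± 0.24) and CFL1 (2.57 ± 0.36), TAGLN2 (2.17 ± 0.16) and ACTB (1.88 ± 0.63) rose, and CALD1 (−0.78 ± 0.17) and FLNA (−0.61 ± 0.30), chosen after their values were seen, fell (median 0.10, camera adjusted p = 0.422). Of 31 glioma signalling genes 8 rose and none fell (8 and 2 adjusted over the list alone), led by the tumour suppressor gene CDKN2A (3.43 ± 0.73, 10.8-fold), with CDK4 at 1.45 ± 0.09 and AKT2 at 1.37 ± 0.48 (other probes 1.39 and 0.30; list median −0.02, camera adjusted p = 0.996). Relative to all genes, the 3 medians were 0.121, 0.082 and −0.035. With 1 array left out they were 0.099 to 0.185, −0.018 to 0.202 and −0.086 to −0.029. The calls of CALD1 and FLNA were lost without replicate 1 (adjusted p from 0.0603 to 0.176). The calls of FLNA and AKT2 were lost without replicate 2 (adjusted p from 0.0602 to 0.191).

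Of 356 ZNF genes 43 rose and none fell (34 and 0 adjusted over the list alone). For this and the following lists, 19.7% of all genes rose and 2.86% fell. Below ZNF157 were ZNF580 (4.03 ± 0.22, 16.4-fold), ZNF444 (3.51 ± 0.52, 11.4-fold) and ZNF615 (2.79 ± 0.59), and the list did not pass (median −0.00082, camera adjusted p = 0.520). Of 49 interferon-stimulated genes 6 rose and 3 fell (6 and 2 adjusted over the list alone), with the chemokine gene CCL5 at 3.06 ± 0.76, the antiviral genes IFITM2 (2.93 ± 0.13), IFITM3 (2.70 ± 0.25) and OAS2 (2.44 ± 0.67) highest, and PARP14 (−0.87 ± 0.19), ISG15 (−0.62 ± 0.21) and IFI44 (−0.52 ± 0.18), chosen after their values were seen, lower (list median −0.09, camera adjusted p = 0.169). Of 32 unfolded protein response genes 6 rose and 1 fell (7 and 5 adjusted over the list alone). PPP1R15A (2.10 ± 0.20), HYOU1 (1.71 ± 0.16), CALR (1.24 ± 0.62) and CHAC1 (1.18 ± 0.20) rose, and the chaperone gene HSPA5, chosen after its value was seen, fell (−1.10 ± 0.48; median −0.21, camera adjusted p = 0.142). Of 32 apoptosis and related genes 4 rose (4 adjusted over the list alone), among them the survival gene BCL2L1 (2.72 ± 0.15), CDKN1A and BCL2 (0.71 ± 0.22; median −0.04, camera adjusted p = 0.323). Relative to all genes, the medians of these 4 lists moved when 1 array was left out: ZNF from −0.020 to between −0.062 and 0.022, interferon from −0.114 to between −0.261 and −0.012, unfolded protein response from −0.229 to between −0.313 and −0.082, and apoptosis from −0.055 to between −0.123 and −0.031. The unfolded protein response list was called lower without replicate 2 (adjusted p = 0.0418) and with slide as a fixed effect (adjusted p = 0.0394). Its medians on replicates 1 to 3 were −0.54, 0.05 and 0.05. The calls of ISG15, IFI44 and BCL2 were lost without replicate 1 (adjusted p from 0.124 to 0.258). The calls of PARP14, ISG15, IFI44, CALR and BCL2 were lost without replicate 2 (adjusted p from 0.0573 to 0.109). The call of IFI44 was lost without replicate 3 (adjusted p = 0.0801).

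Of 25 iron-handling genes 3 rose and 1 fell (3 and 1 adjusted over the list alone). These were the iron hormone gene HAMP (1.47 ± 0.36), the ferritin gene FTH1 (1.43 ± 0.62), EPAS1 (0.71 ± 0.26) and the transferrin receptor gene TFR2 (−0.70 ± 0.07; list median −0.24, camera adjusted p = 0.101). Of 37 extracellular matrix genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), with the protease inhibitor genes TIMP2 (1.58 ± 0.61) and TIMP1 (1.31 ± 0.26), COL6A1 (1.52 ± 0.13, other probe −0.05) and the collagen chaperone gene SERPINH1 (−1.03 ± 0.24), besides P4HA1 (median −0.08, camera adjusted p = 0.0808). Medians below 0 stood beside means above 0 for the ZNF, interferon, unfolded protein response, apoptosis, glioma and astrocyte lists, and camera's direction was lower for all of these but the astrocyte list. Relative to all genes, the iron and matrix medians were −0.255 and −0.103, and −0.227 to −0.131 and −0.266 to −0.109 with 1 array left out. The iron list was called lower with the series matrix values (adjusted p = 0.0413). The matrix list was called lower with median-centred processed signals, the mean of probes, slide as a fixed effect or no replicate block (adjusted p from 0.0439 to 0.049). The call of TFR2 was lost without replicate 1 (adjusted p = 0.0549). The calls of FTH1, EPAS1 and TFR2 were lost without replicate 2 (adjusted p from 0.078 to 0.117). The call of EPAS1 was lost without replicate 3 (adjusted p = 0.0567).

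Markers of neurons were placed higher by camera at its preset correlation only. Of 10 measured, 4 rose (4 adjusted over the list alone): the microtubule regulator STMN2 (3.87 ± 0.82, 14.6-fold), MAP2 (2.13 ± 0.16, other probe 1.01), the glutamate transporter SLC17A7 (1.59 ± 0.16) and the neurofilament gene NEFM (1.17 ± 0.35). Their median was 0.42 (camera adjusted p = 0.0177), with adjusted p = 0.549 with an estimated correlation. No other marker list passed, but the erythroid list was called higher with the processed signals (adjusted p = 0.0235, 1.1 from the median of all genes against 0.50), centred on their median (adjusted p = 0.0245) or from the series matrix (adjusted p = 0.0238). Of 8 oligodendrocyte markers CLDN11 rose (0.93 ± 0.40; 1 adjusted over the list alone, median 0.20, camera adjusted p = 0.639). Of 7 microglia and macrophage markers CD68 (1.13 ± 0.20) and FCER1G (0.83 ± 0.45) rose (3 adjusted over the list alone, median 0.26, camera adjusted p = 0.169). Of 5 astrocyte markers the transcription factor gene SOX9 (1.73 ± 0.58) and GFAP (0.96 ± 0.42) rose (2 adjusted over the list alone, median −0.15, camera adjusted p = 0.939). Of 5 endothelial markers none passed (0 adjusted over the list alone, median −0.05, camera adjusted p = 0.639), with ESAM at 0.19 ± 0.14 (adjusted p = 0.363) and CDH5 at −0.12 ± 0.30 (adjusted p = 0.645). Of 5 erythroid markers the globin genes HBA2 (0.70 ± 0.21) and HBA1 (0.61 ± 0.14), which are near-identical and also counted among the reported targets, rose (3 adjusted over the list alone, median 0.52, camera adjusted p = 0.169). The marker lists were dim, with median log2 intensities from 6.69 (endothelial) to 7.85 (neuron), so their ratios are uncertain. Over the alternatives HBA2 lay between 0.54 and 2.09 and NEFM between 0.97 and 2.42. All RNA came from 1 cell line, so a raised marker does not show that its cell type was present. Relative to all genes, the astrocyte and endothelial medians were −0.172 and −0.068, and −0.122 to 0.050 and −0.121 to −0.026 with 1 array left out. The calls of HBA2 and HBA1 were lost without replicate 1 (adjusted p from 0.0778 to 0.14). The calls of CLDN11, FCER1G, SOX9, GFAP, HBA2 and HBA1 were lost without replicate 2 (adjusted p from 0.050 to 0.148). The calls of FCER1G and HBA1 were lost without replicate 3 (adjusted p from 0.0568 to 0.0673).

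**Figure D3:**
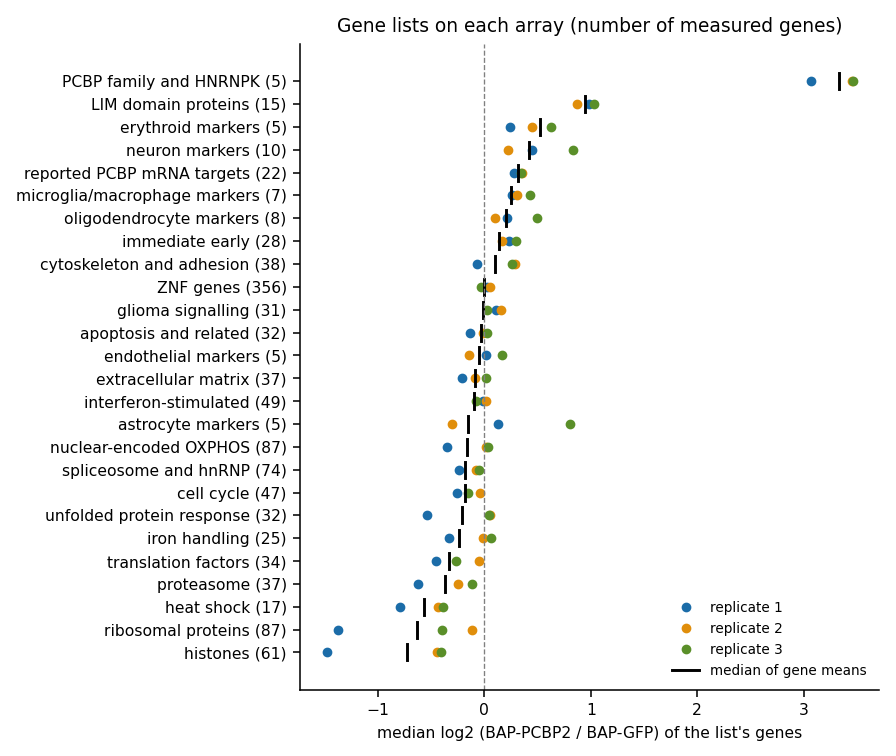
Median log2 ratio of BAP-PCBP2 over BAP-GFP (x axis) of the measured genes of each of the 26 lists, with a point per replicate and a black bar at the median of the genes' means. The ribosomal protein and histone medians lie at −0.63 and −0.73, and the PCBP family median at 3.33.

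Relative to the other genes, 3 of the 26 lists were higher and 8 lower with camera's preset correlation. With an estimated correlation 0 were called, and camera also gave 0 at an unadjusted p under 0.05. fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 5 lists, all higher, namely the PCBP family, reported targets, LIM proteins, immediate early genes and neuron markers, and 22 lists held genes moving in either direction. At an unadjusted p under 0.05, fry placed 10 lists higher and 1 lower. At the same unadjusted threshold in limma, 0 ribosomal protein genes were higher, and 8 ZNF, 1 LIM, 3 glioma signalling and 4 apoptosis genes were lower. So was 1 astrocyte marker, and no gene of the PCBP family list or marker of the other 5 cell types; 0 endothelial markers were higher.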

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

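Control probes that take no part in the comparison gave signal above the negative controls. Of 14 spike-in control probes, 5 exceeded the 99th percentile of the 153 negative-control spots in both channels on all 3 arrays. As the mean over the 6 channel values, E1A_r60_a22 was at 9.57 times that percentile, E1A_r60_a20 at 1.43, E1A_r60_3 at 1.37, E1A_r60_n11 at 1.22 and eQC-40 at 1.13. The value of E1A_r60_a22 rested largely on replicate 2, being 5.37 without it, against 13.2 without replicate 1 and 10.1 without replicate 3. Observed and expected ratios of the spike-in controls correlated at 0.00126, 0.297 and 0.163 on the 3 arrays. With most of these probes near the negative controls, the correlations rest largely on background signal and say little about how well ratios were measured. With 3 samples in the group no test for a single outlying sample was made, and the design holds no second contrast.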

How the results depend on the processing

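PCBP2 stayed between 5.08 and 5.81 and FHL3 between 3.25 and 3.55 under every alternative run. Across named genes, 2144 results kept their direction and side of the threshold, 278 lost their call and 3 reversed; across lists, 471 were the same, 31 weaker, 14 stronger and 1 reversed. Unless a cause is given, the cause was not tested. Median centring without loess gave 1273 higher and 2 lower genes (1271 and 2 of them shared with the reported calls), 1036 and 1 at least 2-fold on every array, 5 lower lists and r = 0.598 between replicates 2 and 3. Processed signals as given gave 1368 lower genes, 120 of 2-fold on every array, r = 0.746 between replicates 1 and 3 and 0.682 between 2 and 3, and CLASRP at −0.20. Centred on their median they gave 2489 and 49 at least 2-fold on every array and CLASRP at −0.046; there another of the gene's 3 probes was the brightest. The series matrix gave 1343 lower and 120 lower by 2-fold. No background subtraction gave 10 lower by 2-fold, and an offset of 10 gave 8, with 5 lower lists. Leaving out 1 array at a time gave 2018 to 3536 higher genes, 73 to 744 lower, 7 to 38 lower by 2-fold, a rule easier to meet on fewer arrays. A variance trend over intensity with robust estimation gave 4309 higher and 560 lower genes, 3529 and 374 of them shared with the reported calls, and ended the call of the spliceosome list. A first run of it had taken the trend over the ratio by mistake, which left no lower gene, and was replaced. Array weights gave 869 lower. Without the replicate block, which ignores the pairing of channels on an array, 229 genes were lower and 3019 higher. An estimated correlation called 0 lists higher and 0 lower, fry 5 and 0, and fry placed the spliceosome list higher although its median lay −0.20 from that of all genes. The mean of a gene's probes put ADAMTS7 at 0.35, its probes being of opposite sign. Leaving out saturated spots changed nothing, since there were none, and slide as a random block was not run because 3 arrays gave no estimate. C content of probes, added after seeing the data, correlated with the ratio at 0.305 with processed signals, 0.308 with median centring and 0.234 to 0.317 with 1 array left out. Dim GFP signal, above background for 53.2% to 69.2% of spots, leaves the fitted ratios of 90 genes that rose uncertain.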

Other observations

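Camera was set before the data were examined. The tests of brightness, of a dye effect alike for all genes and of runs of C were set before their own results. All other tests of this part were chosen only after the result was seen. Besides the genes already described, mitochondrial sequences rose as a class: all 15 tested names were higher, some of them from the same transcript or from neighbouring positions, with a median of 4.62 and a range of 2.10 to 5.71, and 10 rose at least 8-fold. ND6, encoded on the opposite strand to most mitochondrial genes, was at 5.26 ± 0.23, between ND5 (5.07) and ND1 (5.42). Without loess the median was 4.90 and with processed signals 4.55. Among 154 gene families formed from symbol roots, Fisher's exact test found RPL genes less often higher (0 of 60, adjusted p = 0.0012, against 19.7% of all genes), ZNF genes less often higher (42 of 341, 12.3%, adjusted p = 0.041) and keratin genes more often lower (6 of 34, adjusted p = 0.00552, with 6 also higher). Keratin-associated KRTAP genes, 10 of 18 higher, did not pass (adjusted p = 0.060). Fisher's test treats genes as independent, although the estimated correlation between ribosomal protein genes was 0.748. It also takes no account of brightness, and the ZNF list's median was at percentile 22.8 of random lists of the same brightness. These p-values are therefore uncertain.

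Probes richer in C had higher ratios (Spearman 0.293 across 18226 genes, which are not independent; 0.25, 0.198 and 0.338 on the 3 arrays). Over the arrays' mean, G content correlated with the ratio at −0.0743 (bootstrap interval −0.0890 to −0.0607), and at −0.033, −0.21 and 0.018 on replicates 1 to 3. This argued against a bias carried by G and C alike as the whole cause. Total GC content was not tested, and A and T content correlated at −0.159 and −0.077, so a part played by total GC content stays open. Binding of PCBP2 to runs of C may contribute as a hypothesis: among probes with equal C, those with more CCC runs were higher (0.0722, permutation p = 1e-04, the smallest 10000 permutations can give), but this was 0.00625 on replicate 2, and G runs gave 0.0410. A dye effect of C alike for all genes stays open: the 10th percentile rose with C by 0.202 of the rise of the 90th (0.130 to 0.288), and the single dye orientation leaves probe-specific dye effects untested. Binding sites outside the probes were not examined.

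For the mitochondrial transcripts, C content was argued against as the whole cause, since 10000 gene sets with the same C counts had medians up to 1.27 against 4.62, as was brightness, whose matched sets reached 3.81. An equal carry-over of all mitochondrial RNA stays open. The 2 probes on the coding strand of the 16S rRNA gene had a median of 2.33, against 4.89 for the 15 outside this gene, taken from either strand. A probe on the opposite strand of the 16S rRNA gene, counted in neither, was at 2.29. The 2 probes are too few and among the brightest on the arrays, where 2 other probes were also low (2.80 and 2.91). Among the 15, a minus-strand probe (8843 to 8902) was at 4.85 ± 0.49. The plus-strand probe over nearly the same stretch (8831 to 8896) was at 2.80 ± 0.90. The cause of this difference was not tested. Whether PCBP2 binds these transcripts, or mitochondria were recovered with the tagged protein, could not be tested here, so no biological explanation was tested.

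The low ribosomal protein and histone lists could come from probe brightness, but this was argued against: both medians were at percentile 0 of 10000 random lists of the same brightness (matched medians 0.15 and −0.06). Replicate 1, where both medians were lowest, was argued against as the only source, since on the other 2 arrays the higher percentile was 0.08 for ribosomal proteins and 0 for histones. Such lists treat genes as independent and describe these arrays only. With an estimated correlation of 0.748 between ribosomal genes and 0.679 between histone genes, camera called neither list (adjusted p = 0.549). As to the 4116 calls themselves, 1 of the 4 ways to assign the channels to the arrays, the real one, gave as many, and the highest of the others gave 0; 4 are too few for a share under 0.05.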
